A study of Mus musculus with 4 samples.

How the data were processed

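Gene expression was measured in NIH3T3 cells, an established mouse fibroblast line, after transfection with a control siRNA (siControl) or an siRNA against Timp1 (siTIMP1). Per the labels, both siRNAs were carried by apatite nanoparticles, abbreviated sCA there, and the cells were kept in medium with 2% serum. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays with 60-base probes. There were 4 arrays, 2 per group, and each sample was assigned to its group from its title. Replicate numbers used here follow accession order and only name the samples. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

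Per the file headers, all 4 arrays lay on 1 slide and were read in 1 scan, with siControl at positions 1 and 2 and siTIMP1 at positions 3 and 4. Position on the slide and group therefore cannot be told apart. Spot intensity values were deposited as scanner output made with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. Per the file headers, the processed intensity of a spot is background-subtracted and detrended within its array, with no scaling between arrays. The authors' value table holds log2 values, and its scale was found by setting each column against the same array. Each column followed the log2 processed signal with 1 constant subtracted per array, from 6.90 to 6.96, at a Pearson r of 0.99999, and probes with 1 spot deviated by at most 0.005. Its column medians were -3.94 and -3.86 for siControl and -3.99 and -3.91 for siTIMP1. No scale, centring or direction of that table stayed unknown. Probe coordinates are those of the mouse build mm9, per the file headers.

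From the scanner files, log2 of the processed signal minus the array's 75th percentile over non-control spots was computed. Control spots were left out, as were spots marked as non-uniformity or population outliers, 136 to 250 per array. Spots of 1 probe were averaged. A probe was tested when it had a value on all 4 arrays and was well above background on both arrays of at least 1 group, which held for 26015 of 56605 probes. No spot was saturated. Between 45.9% and 52.1% of spots were well above background, the lowest share on siTIMP1 replicate 2. The number of arrays limits the precision.

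Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A gene was represented by its tested probe with the highest mean over all 4 arrays. Probes without a gene symbol were counted as genes under their own names. Names came from the array files. For 32994 probes a RefSeq accession matched the reference gene table, and this updated 1535 symbols. All adjusted p-values for genes come from this limma fit. Gene lists, 36 in number and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Genes named in the text follow a rule fixed at the same time. It takes Timp1, then up to 15 rises and 15 falls of the largest size among called genes whose groups do not overlap and which were well above background on every array. It adds up to 5 genes per direction at background in 1 group, given as bounds, and up to 4 members per list, called members first and then those of smallest p. Clone, predicted and accession names were not used.

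A bound compares the bright group's mean with the dim group's floor. That floor is the mean over its arrays of the higher of the probe's own value and the lowest value among probes well above background.

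The alternatives tried were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over detected probes, a stricter and no filter, eBayes without a trend and with robust settings, outlier spots kept, the mean of a gene's probes, the authors' value table, other thresholds and leaving out each array. With 1 array left in a group, limma pools the spread and assumes that the lone array varies like the others.

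The 7-mer search in the closing section used the mean log2 fold change of each gene's tested probes. It was adjusted for GC content, signal and total probe length by regression. A z was computed for each 7-mer present in at least 20 genes, with 1000 permutations of the genes. Probe sequences were read with Biostrings 2.70.1. Figures were drawn with matplotlib 3.10.9.

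The fit was tested on simulated arrays with the 26015 probes' means and fitted spread, in which 200 genes were changed. It recovered 18% of genes changed 1.5-fold, 56% at 2-fold, 72% at 4-fold and 90% at 8-fold, with 7 false calls among 130. A gene list shifted by 0.5 on the log2 scale and a 7-mer whose probes were shifted by -0.5 were both recovered. This simulation gave every array of a group the same mean, so it holds no array that stands apart. It also drew the noise of each probe independently, with a spread from the fitted trend. It therefore decides nothing about lists whose members vary together, or about the trend itself. In the data, the estimated correlation was up to 0.73 among called lists.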

Results

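Genome-wide transcript levels were compared between NIH3T3 fibroblasts transfected with siTIMP1 (n = 2 arrays) and with siControl (n = 2 arrays), to find which transcripts differ when Timp1 is targeted. Timp1 encodes a secreted inhibitor of matrix metalloproteinases. Fold changes are siTIMP1 relative to siControl on the log2 scale, with the standard error (SE) of the limma fit.

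Timp1, the targeted gene, fell by 5.22 on the log2 scale (SE 0.158, 95% interval -5.63 to -4.82, limma adjusted p = 0.0105). Its probe lies on mouse chromosome X at 20451675 to 20451733 (mm9), and the array files assign it to the Timp1 mRNA. Its normalised log2 signal was 8.35 ± 0.27 (SD, n = 2) in siControl and 3.13 ± 0.21 (SD, n = 2) in siTIMP1, so that siTIMP1 kept 2.68% of the control level. The processed signals were 53297 and 67559 on the siControl arrays and 1840 and 1492 on the siTIMP1 arrays, and all 4 were well above background. The size of the fall moved little when an array was left out, but the adjusted p rose to 0.137 without siTIMP1 replicate 1 and to 0.184 without siTIMP1 replicate 2. It was 0.134 in limma without a mean-variance trend.

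Among 17734 genes, 15 rose and 124 fell with siTIMP1 at the threshold, and 11 of the rises and 68 of the falls were at least 2-fold. Probes without a gene symbol are counted here too, and among the 14291 genes with a symbol 13 rose and 115 fell. Of 59 called genes with a symbol and more than 1 tested probe, 50 had every other probe of the same sign. Another probe was also called in the same direction for 16 of these 59. Atp2a2, the calcium pump of the endoplasmic reticulum, fell by 2.34 (SE 0.105, adjusted p = 0.0181), and its other tested probes had values between -2.18 and -0.86. Lbr, the lamin B receptor of the inner nuclear membrane, fell by 2.03 and Tmsb4x, an actin-binding peptide, fell by 1.76. Another Tmsb4x probe had a log2 fold change of -0.26. Further falls were those of Mreg (-1.89), Cyrib, a regulator of actin (-1.84), Arl5a, a small GTPase (-1.70), Lpp, a focal adhesion protein (-1.65), and Pdhb, a subunit of pyruvate dehydrogenase (-1.61). Mreg kept its call in 6 of 14 alternatives and had a value of -0.79 with normexp background correction, and Lpp had -0.85 and no call with the mean of its probes. Edem1, which acts in the disposal of misfolded glycoproteins, fell by 1.60, and the efflux transporter Abcc4 fell by 1.53. The choline transporter Slc44a1 (-1.50), Eipr1 (-1.50), Bloc1s4 (-1.49) and the olfactory receptor gene Olfr1368 (-2.20) also fell. For Slc44a1, the other tested probes gave -0.95 and 0.33. With normexp background correction the values of Eipr1 and Abcc4 were -0.82 and -0.997, and Cyrib was not called. With the mean of a gene's probes Tmsb4x (-1.01), Slc44a1 (-0.71) and Pdhb (-1.47) were not called, nor was the rise of Ssx2ip (1.05).

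Fewer named genes rose. Ssx2ip rose by 1.31 (SE 0.0885, adjusted p = 0.0225), the chemokine gene Ccl17 by 1.27 and the stress-induced transcription factor gene Atf3 by 1.02. Cnih1, a cargo receptor of the secretory pathway, rose by 1.02 and Maip1 by 0.94. The circadian clock gene Per1 rose by 0.79, Stk40 by 0.65 and Got1, the cytosolic aspartate aminotransferase, by 0.55. Got1 kept its call in 5 of 14 alternatives, and Stk40 was not called with the authors' value table. Ugt3a2 was not well above background in siControl and was at least 19.8-fold higher in siTIMP1. In the other direction, Olfr1348 was at least 7.71-fold lower, Gc at least 5.35-fold, Trpv6 at least 4.49-fold, Sult5a1 at least 4.40-fold and Dnah14 at least 3.97-fold, none of them well above background in siTIMP1. No values under the alternatives were collected for the genes given as bounds, so how far these bounds depend on the background correction was not tested.

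**Figure D1:**
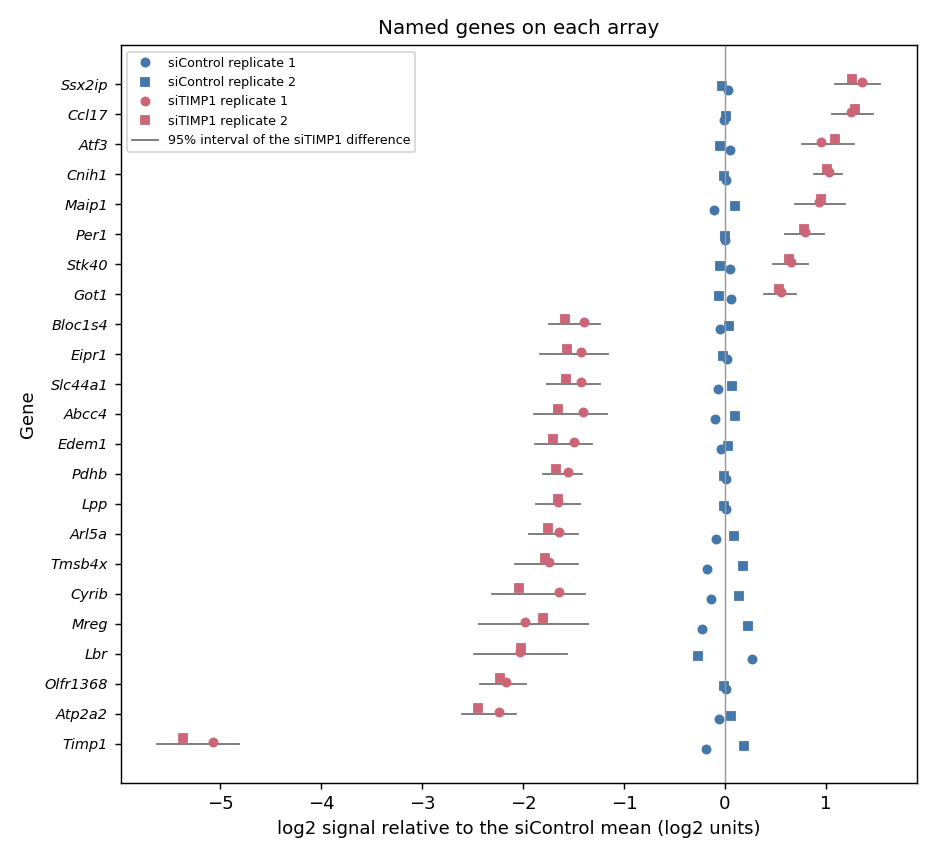
Log2 signal of the named genes on each array (x axis, log2 units) relative to the siControl mean, with 1 gene per line. Blue points are siControl arrays, red points siTIMP1 arrays, and grey lines the 95% interval of the limma difference; Timp1 lies at -5.22 and Ssx2ip at 1.31.

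Over all 26015 tested probes, 179 passed the threshold, 16 higher and 163 lower. At an unadjusted p under 0.05 the balance was the other way, with 2770 probes higher and 2004 lower. The groups did not overlap for 52.99% of probes, where chance gives 33.3% for any single probe. All probes share the same arrays, and position on the slide follows group, so the excess is no test of the siRNA. No gene passed without siTIMP1 replicate 1, without siTIMP1 replicate 2, or in limma without a trend, where 2920, 2692 and 4216 probes had an unadjusted p under 0.05. Without siControl replicate 1 there were 1050 genes and without siControl replicate 2 there were 296, of which 132 and 122 were among the 139 of all 4 arrays.

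Of the 36 gene lists, 6 were called higher and 4 lower with camera. None was called with an estimated correlation, where the lowest adjusted p was 0.505, and fry called 5, 4 of them among these 10 and the other the cytosolic ribosomal proteins. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays, so it had little power to call a list. For p53 targets that correlation was -0.0365, below the preset 0.01, yet the unadjusted camera p went from 0.00067 to 0.063. A call lost there thus does not show that members vary together. The other ways of parting the 4 arrays into pairs called 7 and 10 lists with the same test. Of the 10 called lists, 6 were called in neither of those, and the values below are to be read beside that.

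Immediate early and serum response genes, which cells switch on within minutes of a stimulus, had a median log2 fold change of 0.28 over 35 members (camera adjusted p = 2.7e-06, 0.505 with an estimated correlation, 0.139 by fry). Only Atf3 passed over all probes, while 16 members rose adjusted over the list alone and none fell. Fos had a log2 fold change of 0.90, Dusp1 of 0.89 and Fosb of 0.82. This list was also called when siControl replicate 1 and siTIMP1 replicate 1 were set against the other arrays.

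Targets of p53 had a median of 0.22 over 26 members (camera adjusted p = 0.0080, 0.505 with an estimated correlation, 0.0379 by fry). None passed over all probes, and 7 rose and 1 fell adjusted over the list alone. Eda2r had a log2 fold change of 1.105 (0.39 with normexp background correction), Btg2 of 0.81, Plk3 of 0.50 and Aen of 0.32. Lysosome and autophagy genes had a median of 0.15 over 31 members (camera adjusted p = 0.0281, 0.505 with an estimated correlation, 0.0369 by fry). None passed over all probes, and 8 rose and 1 fell adjusted over the list alone. Neu1, a lysosomal sialidase, had a value of 0.60, and the proton pump genes Atp6v1a and Atp6v1h had 0.34 and 0.27. The adjusted p of that list was 0.105 with quantile normalization, where its median was 0.096, 0.0560 with the percentile over detected probes and 0.0812 without siTIMP1 replicate 2, where its median was 0.09. Genes of the unfolded protein and integrated stress response had a median of 0.23 over 34 members (camera adjusted p = 0.0087, 0.505 with an estimated correlation, 0.206 by fry). Atf3 rose and Edem1 fell, and 6 members rose and 2 fell adjusted over the list alone. Hspa5 had a value of 0.25 and Ero1a of -0.90. Without siTIMP1 replicate 2 the adjusted p of this list was 0.0513.

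The RNA interference machinery was called lower, with a median of -0.16 over 13 members (camera adjusted p = 0.0092, 0.505 with an estimated correlation, 0.0369 by fry). Tnrc6a, a partner of Argonaute proteins, fell by 0.998, and Ago3 and Ago1 had values of -0.79 and -0.48. Adjusted over the list alone, 4 members fell and 2 rose. The 2 that rose, Xpo5 (0.33) and Tarbp2 (0.27), are both given, which takes this list past the 4 members of the naming rule. The TIMP family list holds Timp1 itself and is no independent evidence (camera adjusted p = 0.0092, 0.505 with an estimated correlation, 0.0379 by fry). Timp3 had a log2 fold change of -0.31 (adjusted p = 0.0974, or 0.0039 adjusted over the list alone) and Timp2 of 0.03. G1/S cell cycle genes had a median of -0.09 over 30 members (camera adjusted p = 0.0329, 0.505 with an estimated correlation, 0.380 by fry), with Rrm2 at -0.62 and Mcm2 at -0.43. None passed over all probes, and 1 rose and 4 fell adjusted over the list alone. The adjusted p of this list was 0.132 without siControl replicate 1, with a median of -0.016, and 0.0592 and 0.106 without siTIMP1 replicate 1 and 2. With normexp background correction its median was -0.045 (adjusted p = 0.0470).

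In 3 called lists the medians of the siControl arrays differed from each other by more than the group means did. In the TIMP family they differed by 0.60, against -0.575 between groups, and that list was not called without siControl replicate 1 (adjusted p = 0.0743, median -0.17, against -0.52 on all arrays). Its median was -0.88 without siControl replicate 2 and -0.31 with no filter. Oxidative stress and NRF2 targets had a median of -0.27 over 21 members (camera adjusted p = 6.3e-06, 0.837 with an estimated correlation, 0.380 by fry), and Me1 and Sod2 fell by 1.23 and 1.13. The list medians of the siControl arrays differed by 0.34, and the group means of these medians by -0.32. The median was -0.45 without siControl replicate 1 and -0.12 without siControl replicate 2. SREBP and sterol synthesis genes had a median of 0.23 over 27 members (camera adjusted p = 0.0196, 0.929 with an estimated correlation, 0.685 by fry), and none passed over all probes or adjusted over the list alone. Here the siControl arrays differed by 0.60, and the median was 0.53 without siControl replicate 1 and -0.06, with no call, without siControl replicate 2. Its adjusted p was 0.0513 without siTIMP1 replicate 2 and 0.0668 with the mean of a gene's probes. The latter 2 lists were also called in both other splits of the arrays.

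**Figure D2:**
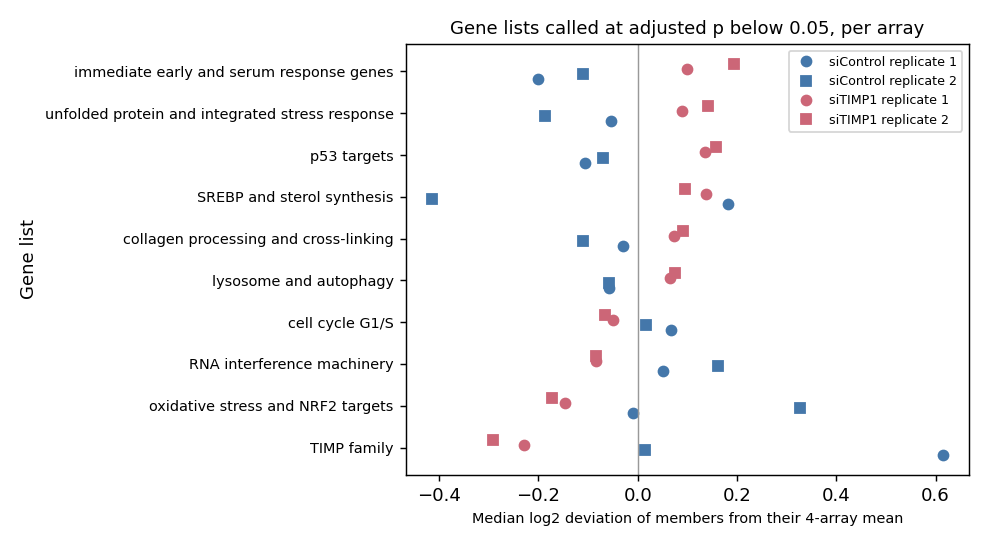
Median log2 deviation of list members from their mean over the 4 arrays (x axis, log2 units), for the 10 called lists. Each point is 1 array, blue for siControl and red for siTIMP1; for SREBP and sterol synthesis, siControl replicate 2 lies at -0.41 and the other 3 arrays between 0.09 and 0.18.

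Matrix metalloproteinases, a family that includes proteases inhibited by TIMP1, had 7 measured members and no call as a list (camera adjusted p = 0.179). Mmp9 and Mmp19 had log2 fold changes of -0.63 and -0.39, which passed adjusted over the list alone only. Among ADAM and ADAMTS proteases, Adam10 fell by 1.09 (adjusted p = 0.0281, or 0.0837 with the mean of its probes), and the list was not called (camera adjusted p = 0.972). Collagens were not called (camera adjusted p = 0.171), and 3 of 25 members, Col7a1 (0.54), Col8a1 (0.48) and Col4a1 (0.30), passed adjusted over the list alone. Matrix glycoproteins and proteoglycans were not called (36 members, camera adjusted p = 0.844), and their median of 0.04 and the test differed in sign. Adjusted over the list alone, Nid1 (-0.68), Thbs2 (-0.58) and Lum (-0.37) fell and Mfap2 rose. No size is given for Mfap2, since its siControl mean lay below the floor used for bounds. Collagen processing and cross-linking genes were called higher (median 0.17, camera adjusted p = 0.0442, 0.837 with an estimated correlation, 0.394 by fry), while P4ha2, a collagen prolyl hydroxylase, fell by 0.72. That list kept its call in 8 of 16 alternatives. Its adjusted p was 0.0618 with quantile normalization, 0.0720 with the percentile over detected probes and 0.0727 with the stricter filter. It was 0.354 without siControl replicate 2, where the median was 0.096, and 0.0525 and 0.186 without siTIMP1 replicate 1 and 2. The list was also called in 1 other split of the arrays. Diablo, an activator of apoptosis, fell by 1.04, a call kept in 7 of 14 alternatives, and its value was -0.66 with the mean of its probes. Apoptosis regulators were not called as a list (camera adjusted p = 0.835). The lists not called had camera adjusted p-values from 0.0581 to 0.999, among them the markers of other cell types.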

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

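All alternatives here were fixed before the data were examined. Timp1 kept its direction under each, with log2 fold changes from -5.41 to -5.04 when 1 array was left out, and without a variance trend its value was -5.22 at an adjusted p of 0.134. For genes higher, the count of 15 became 107 with no filter, 53 with robust eBayes, 0 without a trend, 151 at an adjusted p under 0.1 and 69 at an unadjusted p under 0.05 with 2-fold and no overlap. For genes lower, the count of 124 became 258 with no filter, 0 without a trend, 72 with the mean of a gene's probes, 68 with a 2-fold minimum, 281 at an adjusted p under 0.1 and 216 at the unadjusted threshold. Leaving out 1 array gave 0 to 408 genes higher and 0 to 642 lower, and 0 in both directions without either siTIMP1 array. Without 1 siTIMP1 array the spread rests on the siControl pair, and without 1 siControl array on the siTIMP1 pair. As many arrays remain in either case, so their number does not account for the difference between these cases. Its part in the change from the fit on all arrays was not separated. The median absolute difference between arrays was 0.145 within siControl and 0.118 within siTIMP1. The cause of these changes was not tested. Gene lists called numbered 0 with an estimated correlation, 5 with fry and 5 to 12 when 1 array was left out. Without siControl replicate 2, the medians of SREBP and sterol synthesis (-0.065, against 0.53 without siControl replicate 1) and of G2/M genes (-0.077, against 0.27) turned sign. Among named genes, 2029 values under alternatives stayed on their side of the threshold, 107 lost and 98 gained a call. None that was called in the main fit or under the alternative changed sign. Sign changes of values called in neither were not counted. These counts leave out Timp1 and the genes given as bounds. The share of falls among called probes, 91.1%, was 90.2% with quantile normalization, 90.8% with normexp and 91.6% with the percentile over detected probes. It was lower with no filter (72.9%), with robust eBayes (80.3%), at an adjusted p under 0.1 (68.0%), at the unadjusted threshold (77.3%), and without siControl replicate 1 (63.5%) or 2 (74.7%). The slide could not be fitted as a block, since there was 1 slide. No paired analysis was possible because the groups share no number in the labels. Probes not well above background limit what can be seen of dim genes.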

Other observations

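Tests chosen after the results were seen are those in the other splits of the arrays, those on CTGTTTA and TGTTTAA or the GAA repeats alone, the difference from genes without the 7-mers, and the shares of falls among probes of smallest p and without the genes that have the 7-mers in their probes. The lowest z, the held-out genes, the reverse complements, the other probes of all 6 7-mers and the share of falls with quantile normalization were written down beforehand as tests.

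The siControl arrays differed from each other in several gene groups. Medians of mitochondrially encoded genes differed by 0.47 between them, those of G2/M genes by 0.32 and those of replication-dependent histones by 0.26, while the siTIMP1 arrays differed by 0.04, 0.02 and 0.02. In each of these lists siControl replicate 2 was the array farthest from the others.

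Over 17733 genes without Timp1, 6 of 13927 7-mers in the 60-base probe sequences had a z below -4.87, the 5% point of the lowest z in 1000 permutations, with GAAGAAG lowest at -12.64, and 1 in the other direction, GTGTGTG at 4.76, lay above the 95% point of the highest z, 4.57. Chance among many 7-mers is argued against by random splits of the genes into equal parts. There, 7-mers found in 1 part had a mean z of -7.235 in the other over 20 draws. Base composition was to be tested by the reverse complements, whose lowest z was -0.5702. The reverse complements share GC content, which the regression had already adjusted for, so little of a GC effect was left for them to show. They do not share purine content, on which they decide nothing. An array that stands apart may account for the GAA repeats and GAGAGAG, since z of GAAGAAG reached 15.73 in another split, and its probes lay 0.36 above the rest on siControl replicate 2. Single-probe effects such as cross-hybridisation stay open too. This holds for Arl5a and Gc, named above among the falls, which have a GAA repeat in a tested probe. GAA repeats were in probes of 8 of 123 genes that fell (6.5%), against 5.29% of all tested genes. Other probes of genes with any of the 6 7-mers had a mean adjusted fold change whose 95% interval, up to 0.0178, held 0. So did that of the GAA repeats alone, up to 0.0487. The difference of the pooled set from genes without the 7-mers, -0.025, had an interval (-0.0485 to -0.0023) that did not. That set includes the genes with CTGTTTA or TGTTTAA, whose other probes had a mean of -0.092. The mean was 0.024 for other probes of the GAA repeats and 0.021 for genes without the 7-mers. Permuting genes does not cover a difference between arrays, so neither the permutations nor these splits speak against that source.

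CTGTTTA and TGTTTAA, which overlap by 6 bases, behaved differently from the repeats. Their z was -7.20 and -6.74, and in the other splits its size was at most 1.389, which argues against siControl replicate 2 as the source. Other probes of the same genes, lacking both 7-mers, had a mean adjusted log2 fold change of -0.09 with a 95% interval up to -0.03877, which argues against single-probe cross-hybridisation. With only the brightest probe of each gene in the search, z was -8.63 for CTGTTTA and -7.28 for TGTTTAA, below the 5% point of -4.83. The mean of the other probes was then -0.13 with an interval up to -0.0497. The pair itself had been chosen in the search over all probes, so the other probes had a part in that choice. Of 123 genes that fell, 16 had at least 1 of them in a tested probe, against 307 of 17733 tested genes. This is a description, as the 7-mers were found in the same fold changes. Among the 16 were Atp2a2, Mreg, Cyrib, P4ha2 and, named after its value was seen, Nfe2l2 (-0.64), which encodes NRF2. Pairing of an siRNA seed with these sites is a hypothesis that may explain this part of the falls; the siRNA sequences are not given in the sources used here, and an effect of lower Timp1 itself was not separated from it.

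Falls made up 91.1% of the called probes. Scaling of the arrays is argued against, since the share was 90.23% with quantile normalization. Without siTIMP1 replicate 2, falls were 63.13% of the 179 probes of smallest p, and 48.0% without siTIMP1 replicate 1, so a part played by single arrays cannot be told apart from the groups with 2 arrays each. The lowest z, -12.64, belongs to a repeat that also differs between the siControl arrays and so decides nothing about seeds, and without the genes that carry any of the 6 7-mers the share of falls was still 89.7%. The real split called 179 probes and each of the other splits 3, but 3 splits are too few for a share under 0.05.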
